A study of Rattus norvegicus with 12 samples.

How the data were processed

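Total RNA from 12 hearts of Sprague-Dawley rats, an outbred laboratory stock, had been hybridised to Illumina bead arrays, on which each probe is a short sequence that binds the labelled copy of 1 transcript. Per the labels' protocols, RNA was extracted with Trizol, cleaned on a column with DNase treatment, checked for quality, and copied into biotin-labelled cRNA. The labels put 4 hearts in each of 3 groups, namely control hearts without added load, hearts under phasic systolic overload and hearts under phasic diastolic overload. They do not give the length of loading, the chamber sampled, or the slide on which each array lay, and they do not say outright that each heart came from another animal. The p-values measure the spread between these samples, which may be in part technical.

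The deposited non-normalized table gives 1 intensity per probe and array on a linear scale, and per the file headers these values are not normalized. From the values, no background had been subtracted. The same deposited table gives a detection p-value per probe and array, in whole steps of 1/825, which compares the probe with the array's negative controls. A second deposited table holds the same intensity values after quantile normalization on a linear scale. This normalization was worked out from the values (column medians of 96.8 to 96.9, rank correlation with the raw columns of 1.00), and the software behind either table is not given in the sources used here. All columns of per-sample values were mapped to a sample, and no 2 arrays held identical values.

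Gene names came from the platform annotation supplied with the probe identifiers. Of 22523 probes, 13793 had 1 gene symbol, 0 had several and 8730 had none. Of the named probes, 13752 had an Entrez identifier found in the gene table of rat assembly GRCr8, and 0 symbols changed on update. Probes without a symbol were tested and are counted, but not named.

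Background was corrected and arrays were quantile normalized with neqc in limma 3.58.1 (R 4.3.3), which infers the negative controls from the detection p and adds an offset of 16 before the log2. Probes with a detection p under 0.05 on at least 4 of 12 arrays were tested, which left 10234 probes, 7473 with a symbol. A linear model with 1 mean per group was fitted to all 12 arrays (lmFit, then eBayes), and the 3 pairwise contrasts were tested. P-values were adjusted by Benjamini-Hochberg within each contrast at a threshold of 0.05. A difference is on the scale of normalized log2 intensity, and a fold is 2 to that power, which understates changes of dim and of near-saturated probes. For arrays, the number of hearts limits the precision. The median standard error of a log2 difference was 0.13.

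The 42 lists of genes, covering stress pathways, load-responsive genes, metabolism, signalling and markers of cardiac and other cell types, were fixed before the data were examined, together with the tests and the rule for named genes. Each gene was represented by its tested probe with the highest mean, which gave 7348 genes. The 39 lists with at least 5 tested genes were tested in 3 contrasts with camera at a preset correlation between genes of 0.01, adjusted over all 117 tests. Camera asks whether the genes of a list rank higher or lower than all other genes. Camera with a correlation estimated per list and fry were run beside it. Fry is a rotation test with another null than camera, that no member of the list changed, so it is not a repeat of the camera test. Marker lists of neutrophils (2 tested genes), mast cells (4) and epicardium (1) were too short to test. A list score per heart is the mean over the list's genes of the log2 intensity minus that gene's mean over the 12 hearts. Scores were compared by a two-sided exact permutation test, chosen after seeing the data, whose smallest possible p for 4 hearts against 4 is 0.0286.

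The rule for named genes took 12 load- and stress-responsive genes in every contrast, the 10 genes with the smallest p where fewer than 10 probes passed (values only), and for each list called by camera without a passing member, the 2 members with the largest absolute log2 difference. One of the 12 fixed genes, Hspa1b, was detected on 0 of 12 arrays and was not tested. A probe not detected on any array of a group has only a bound there, given as "at least N-fold" against the lowest detected signal of each array. The bound concerns the means of the measured hearts and leaves out the spread between hearts.

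The pipeline was tested on simulated data made from the probe means and variances. In 20 simulated comparisons of systolic overload with control over 10234 probes, 200 of them changed, 46.2% of probes changed by log2 0.5 were found, 92.6% at log2 1, 98.3% at 1.5 and 99.6% at 2, with 9.50 false calls on average. For lists, 39 unshifted lists whose members varied together as strongly as estimated here gave 3.60 calls per contrast on average with the preset correlation and 0 with an estimated one, over 7348 genes. A list of independent genes shifted by log2 0.25 was found in 100% of runs by both. How often a shifted list with correlated members would be found was not simulated.

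Alternatives were other background and normalization methods, the deposited normalized values, other detection filters, fits with only the 2 groups compared, array weights, a trended robust prior, the replicate number as a block, other thresholds, and each array left out in turn. Alternatives with the leading residual component as a covariate, with 3 arrays left out together, and with list scores were added after seeing the data. A slide block was planned, but no source used here gives the slides, so it was not run.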

Results

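Gene expression was measured in 12 rat hearts on bead arrays with 22523 probes, in 4 hearts without added load (control), 4 under an overload confined to systole, when the ventricle contracts, and 4 under an overload confined to diastole, when it fills. The series title asks whether load in one phase of the cardiac cycle acts on gene expression differently from load in the other. Between 9249 and 9931 probes were detected per array, which is 41.1% to 44.1% of the probes, and raw median intensities ran from 86.3 to 115.5, with the highest in control 4. Normalized arrays correlated with one another at 0.984 to 0.992. The leading principal component held 23.1% of the variance and did not follow the groups, with control 1, control 2, diastolic overload 1 and, less far out, systolic overload 3 at one end.

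In systolic overload against control, genes of the unfolded protein response, which handles misfolded proteins in the endoplasmic reticulum, were higher as a group by camera at a preset correlation, but not with an estimated correlation (adjusted p = 0.55). Of 19 tested members, 18 had a higher mean under systolic overload, with a median log2 difference of 0.23. Dnajb9, a co-chaperone of the endoplasmic reticulum, stood at 9.67 ± 0.16 against 9.13 ± 0.09 in control (log2 intensity, SD, n = 4 each), or 1.45-fold (95% interval 0.27 to 0.81 in log2). Manf, a secreted protein induced by stress of this organelle, stood at 10.10 ± 0.06 against 9.65 ± 0.19, or 1.37-fold. In both genes all 4 overloaded hearts lay above all 4 controls. Hspa5, the main chaperone of the organelle, stood at 13.77 ± 0.04 against 13.44 ± 0.07.

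Camera called the unfolded protein response list higher (adjusted p = 2.64e-08), and the call was lost at adjusted p = 0.55 with an estimated correlation. Fry, which asks another question, whether the members changed at all and not whether they differ from other genes, gave an adjusted p of 0.11, and 0.0042 for change in either direction. No member passed over all probes. Adjusted over the list alone, 4 members were higher, namely Dnajb9, Manf, Hspa5 and Creld2, of which the last 2 are named outside the rule for named genes, after their values were seen. Such counts, here and below, add no separate support for a list singled out by camera on the same values. Uncalled lists had such members too, with 2 glucocorticoid-responsive, 2 ubiquitin-proteasome and autophagy and 1 glycolysis gene higher in this contrast. The list scores of the 4 systolic hearts, 0.08 to 0.27, all lay above those of the controls, −0.15 to −0.05. The exact permutation p was 0.0286, the smallest possible, and 0.48 adjusted. NRF2 targets, ubiquitin-proteasome and autophagy genes, and cardiomyocyte markers reached the same exact permutation p in this contrast. With median scaling in place of quantile normalization, the list's median was 0.02 while the median of all tested probes was −0.17.

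No single probe passed the test under systolic overload, which does not show that none changed. With limma, 0 of 10234 probes passed (smallest adjusted p = 0.52), while 593 had an unadjusted p under 0.05, against 511.7 expected by chance, and 0 passed under each alternative setting run. Groups did not overlap for 3.50% of probes, against 2.86% by chance. The 95% interval of the difference lay within 2-fold in either direction for 97.2% of probes.

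The gene with the smallest p was Smoc2, a matrix-associated calcium-binding protein, at 8.12 ± 0.21 under systolic overload and 8.89 ± 0.16 in control (log2 difference −0.77 ± 0.14 SE, adjusted p = 0.52), lower in 4 of 4 hearts. Lower means were also found for Adamts7, a metalloproteinase (−0.57), Tcf7l1, a transcription factor of the Wnt pathway (−0.61), Nudt16l1 (−0.61, above background in 1 of 4 systolic hearts) and Ninj2 (−0.47). Higher means were found for Lrrc10, a cardiac leucine-rich repeat protein (0.54), Tob1, an antiproliferative protein (0.52), and Slc66a1, a lysosomal amino acid transporter (0.40, above background in 2 of 4 controls). Fyttd1 was not well above background in any control heart and Nccrp1 in any systolic heart, so that their measured means differed by at least 1.19-fold and 1.18-fold. None of these genes passed the test.

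Camera called 4 further lists in this contrast at its preset correlation, and none of them with an estimated correlation. Targets of NRF2, the regulator of the antioxidant response, were higher (14 of 18 members, median 0.06, adjusted p = 0.036; adjusted p = 0.57 with an estimated correlation), with Nqo1 at 0.36 and Ftl1 at 0.33, and so were heat shock proteins (13 of 19, median 0.08, adjusted p = 0.038, and 0.55 with an estimated correlation), in which Hspa2 stood at 0.47 but Dnajb1 at −0.48. Interferon-stimulated genes were lower (21 of 22, median −0.47, adjusted p = 0.00042, and 0.79 with an estimated correlation), with Ifi44 at −1.05 and Mx1 at −0.98, and endothelial markers were lower (11 of 14, median −0.19, adjusted p = 0.038, and 0.57 with an estimated correlation), with Emcn at −0.44 and Plvap at −0.47. Plvap was at 7.65 and 7.22 in controls 1 and 2, and at 5.89 and 5.85 in controls 3 and 4. The systolic hearts, at 5.80 to 6.38, all lay below controls 1 and 2, and the lowest of them also lay below controls 3 and 4. Adjusted over the list alone, 1 endothelial marker was lower and 0 members of the other lists passed. Leaving out 1 array ended the call for endothelial markers in 8 of 12 fits, for heat shock proteins in 7, for NRF2 targets in 2 and for interferon-stimulated genes in 1, the fit without control 2 (median −0.23, adjusted p = 0.092). With 1 array left out, medians ran from −0.28 to −0.09 for endothelial markers, 0.04 to 0.13 for NRF2 targets and −0.69 to −0.23 for interferon-stimulated genes. Interferon scores were 0.62 and 0.85 in controls 1 and 2, −0.43 and −0.17 in controls 3 and 4, and −0.65 to 0.30 in the systolic hearts.

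**Figure D1:**
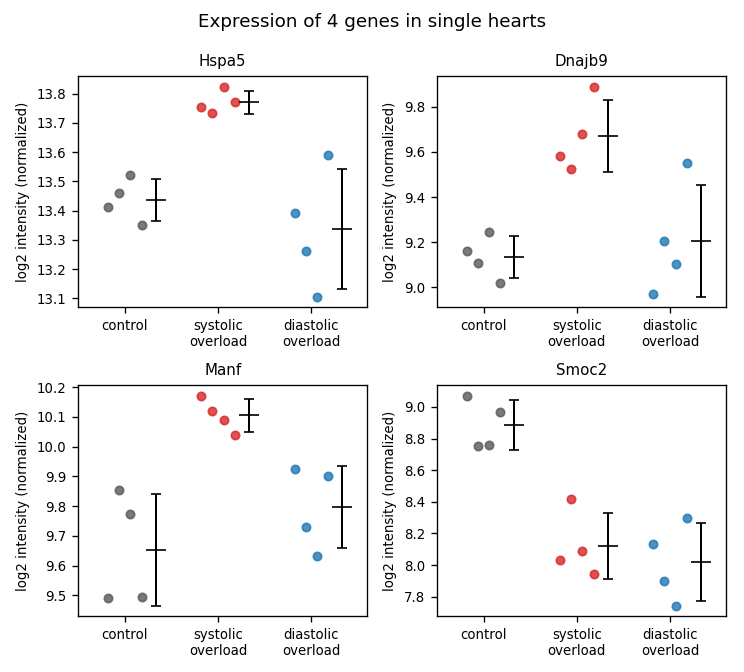
Normalized log2 intensity of Hspa5, Dnajb9, Manf and Smoc2 by group, with a point for each of the 4 hearts and a mean with a bar of 1 SD beside them. Hspa5 was at 13.73 to 13.82 in the systolic overload hearts, above the control hearts, and Smoc2 was at 7.74 to 8.42 in overloaded hearts of either kind and at 8.75 to 9.07 in control hearts.

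In diastolic overload against control, camera at its preset correlation called markers of immune cells and cardiac load genes higher as groups. None of these calls held with an estimated correlation (adjusted p = 0.57 for macrophage and for lymphocyte markers and 0.55 for load genes). Of 12 tested macrophage and monocyte markers, 11 had a higher mean (median log2 difference 0.37), among them Adgre1, a surface receptor of macrophages, at 6.12 ± 0.24 against 5.57 ± 0.12 (1.47-fold), and C1qa, a complement component, at 0.51. Of 12 lymphocyte markers 10 were higher (median 0.20), with Cd3d, a chain of the T-cell receptor complex, at 6.35 ± 0.24 against 5.47 ± 0.31 (1.83-fold, SD, n = 4 each) and Cd8a at 0.66. Genes of the cardiac load and fetal program had higher means in 14 of 18 members (median 0.20), with Hbegf, a growth factor, at 0.50 but Gdf15, a stress-induced cytokine, at −0.52.

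Camera called these 3 lists at adjusted p = 0.00042, 0.0029 and 0.0037 with the preset correlation. Adjusted over the list alone, 1 macrophage marker and 1 lymphocyte marker were higher, and 0 load genes. The macrophage call ended without diastolic overload 1 (median 0.10, adjusted p = 0.13), and the lymphocyte and load calls without control 4 (medians 0.15 and 0.14, adjusted p = 0.0795 and 0.0636). With 1 array left out, medians ran from 0.10 to 0.51 for macrophage markers, 0.10 to 0.33 for lymphocyte markers and 0.14 to 0.36 for load genes. Macrophage markers were also higher in 9 of 12 members under systolic overload, without a call (median 0.23, camera adjusted p = 0.26).

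Camera called 4 other lists at its preset correlation, and none of them with an estimated correlation. Endothelial markers were lower in 12 of 14 members (median −0.23, adjusted p = 0.022, and 0.57 with an estimated correlation), with Cldn5 at −0.53 and Sox18 at −0.51 (above background in 2 of 4 diastolic hearts). Hypoxia-inducible genes were lower in 12 of 16 (median −0.06, adjusted p = 0.049, and 0.55 with an estimated correlation), with Vegfa, the vascular growth factor, at 9.68 ± 0.29 against 10.22 ± 0.15 and the glycolytic enzyme Eno1 at −0.57, which were the 2 members lower when adjusted over the list alone. Fatty acid oxidation genes were lower in 23 of 32 (median −0.07, adjusted p = 0.025, and 0.79 with an estimated correlation), with Angptl4 at −0.71 and Acot1 at −0.68, and cardiomyocyte markers were higher in 11 of 14 (median 0.08, adjusted p = 0.038, and 0.55 with an estimated correlation), with Myl2 at 0.40 and Tnni3 at 0.22. Groups overlapped for Cldn5 (9.18 to 11.19 in diastolic, 9.66 to 11.10 in control hearts) and Angptl4 (4.97 to 6.95 against 5.45 to 7.76). Tnni3, at 14.36 in control, was near the top of the array's range, where differences can be compressed. Leaving out 1 array ended the calls of these 4 lists in 4, 9, 4 and 7 of 12 fits, in this order. Medians then ran from −0.31 to −0.14 for endothelial markers, −0.10 to −0.03 for hypoxia-inducible genes and −0.15 to −0.04 for fatty acid oxidation. Cardiomyocyte markers were also higher in 10 of 14 members under systolic overload, without a call (median 0.12, camera adjusted p = 0.17). Wnt and Notch signalling genes were lower under diastolic overload in 11 of 14 members, without a call (median −0.09, camera adjusted p = 0.17). Their exact permutation p was 0.0286 (adjusted 0.48), and fry gave an adjusted p of 0.11, as for the unfolded protein response under systolic overload.

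No single probe passed the test under diastolic overload either. With limma, 0 of 10234 probes passed (smallest adjusted p = 0.34), 562 had an unadjusted p under 0.05, and 0 passed under each alternative setting run. The interval of the difference lay within 2-fold for 97.3% of probes. Of the 10 genes with the smallest p, 9 are named here. Smoc2 again had the smallest p, at 8.02 ± 0.25 against 8.89 ± 0.16 in control (log2 difference −0.87 ± 0.14 SE, adjusted p = 0.34), lower in 4 of 4 hearts. Mpzl1 had a lower mean (−0.50), as did Or10ag54b, annotated as an olfactory receptor (−0.53). Ywhag, a 14-3-3 protein, Lyve1, a hyaluronan receptor of lymphatic vessels and some macrophages, and Hcst, a signalling adaptor of lymphocytes, had higher means (0.78, 0.72 and 0.64). Against the same controls, systolic means were also higher for Lyve1 (8.11 against 7.58), Ywhag (7.58 against 7.18) and Hcst (6.83 against 6.61). They were also lower for Mpzl1 (6.98 against 7.30) and Or10ag54b (5.41 against 5.84). Frs2 and Slc43a2 were not well above background in any control heart, and their measured means differed by at least 1.33-fold and 1.2-fold.

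The 11 measured load- and stress-responsive genes fixed in advance did not pass in any contrast. Ankrd1, Nppb, Myh6 and Myh7 were near the top of the array's range in all groups, where bead signals can be compressed, with Ankrd1 at 14.80 ± 0.05 in control, 14.88 ± 0.09 under systolic and 14.91 ± 0.02 under diastolic overload. Acta1, skeletal alpha-actin, was at 13.54 ± 0.34 in control, 13.85 ± 0.22 under systolic and 13.93 ± 0.37 under diastolic overload (adjusted p = 0.86 and 0.92 against control). Nppa, the atrial natriuretic peptide, ranged from 10.46 to 14.46 among the 12 hearts, or 16-fold, with differences from control of −0.44 and −0.00063. The highest Nppa value lay within the range of Nppb (14.25 to 14.66), so this fold may be understated. Fos, Egr1, Atf3 and Ccl2 differed from control by at most 0.15 in log2 in either overload, and Il6 by −0.48 and −0.44.

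In systolic against diastolic overload, which asks directly whether the phase of the load mattered, unfolded protein response genes were higher under systolic overload by camera at a preset correlation, but not with an estimated correlation (adjusted p = 0.55). Of 19 members 16 had a higher mean (median log2 difference 0.21), with Hspa5 at 13.77 ± 0.04 against 13.34 ± 0.21 (1.35-fold) and Dnajb9 at 9.67 ± 0.16 against 9.21 ± 0.25. All 4 systolic hearts lay above all 4 diastolic hearts for Hspa5, and 3 of 4 for Dnajb9. Camera called the list at adjusted p = 6.44e-07, and the call was lost at 0.55 with an estimated correlation. Fry gave an adjusted p of 0.13, and 0.0042 for change in either direction. Adjusted over the list alone, 5 members were higher, namely Hspa5, Dnajb9, Calr, Manf and Canx, of which Calr, Manf and Canx are named outside the rule, after their values were seen. The exact permutation p of the list scores was 0.057 (adjusted 0.70), and without diastolic overload 3 the median was 0.13. Lists of MAPK cascade kinases and of PI3K-AKT-mTOR signalling reached an exact permutation p of 0.0286 in this contrast (adjusted 0.48).

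Camera called 8 further lists in this contrast at its preset correlation, and none of them with an estimated correlation. Cardiac load and fetal genes were lower under systolic overload (17 of 18, median −0.17, adjusted p = 0.0037, and 0.55 with an estimated correlation), with Hbegf at −0.87 and the matricellular protein Ccn2 at −0.75. Lymphocyte markers were lower (10 of 12, median −0.21, adjusted p = 0.0029, and 0.57 with an estimated correlation), with Cd8a at −0.98 and Cd3d at −0.71, and so were macrophage markers (10 of 12, median −0.14, adjusted p = 0.048, and 0.79 with an estimated correlation), with Fcgr3a at −0.79 and Aif1 at −0.58. Extracellular matrix genes were lower (23 of 30, median −0.14, adjusted p = 0.033, and 0.85 with an estimated correlation), with Postn at −1.32 and Col3a1 at −0.81. Fibroblast markers had lower means in 9 of 14 members without being called (adjusted p = 0.34), and diastolic overload 1 had the highest score of both lists (0.58 and, for matrix, 0.78). Also lower were interferon-stimulated genes (19 of 22, median −0.24, adjusted p = 0.025, and 0.87 with an estimated correlation), with Ifi44 at −0.64 and Psmb8 at −0.57. Immediate early genes were lower (15 of 21, median −0.09, adjusted p = 0.048, and 0.57 with an estimated correlation), although members went both ways, with Ier3 at −0.80 and Klf2 at 0.55. Fatty acid oxidation genes were higher (28 of 32, median 0.09, adjusted p = 0.0039, and 0.62 with an estimated correlation), with Acot1 at 0.93 and Pdk4 at 0.56, and glucocorticoid-responsive genes were higher (10 of 15, median 0.13, adjusted p = 0.038, and 0.57 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 1.04 and Lcn2 at 0.96.

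Without diastolic overload 1, 6 of these 8 calls ended, all but those of load genes and lymphocyte markers. The median was then −0.02 for extracellular matrix (adjusted p = 0.97), 0.03 for macrophage markers (0.80), 0.10 for interferon-stimulated genes (0.97), −0.02 for immediate early genes (0.11), 0.06 for fatty acid oxidation (0.070) and 0.19 for glucocorticoid-responsive genes (0.079). Leaving out 1 array ended the call in 8 of 12 fits for macrophage markers and immediate early genes, 6 for glucocorticoid-responsive genes, 5 for interferon-stimulated genes, 3 for extracellular matrix and fatty acid oxidation, 1 for lymphocyte markers and 0 for load genes. The median of the load genes nevertheless ran from −0.25 to −0.06 with 1 array left out, with a highest adjusted p of 0.0496. Other medians ran from −0.30 to 0.03 for macrophage markers, −0.17 to −0.02 for immediate early genes, 0.06 to 0.19 for glucocorticoid-responsive genes, −0.54 to 0.10 for interferon-stimulated genes, −0.29 to −0.02 for extracellular matrix, 0.06 to 0.17 for fatty acid oxidation and −0.31 to −0.13 for lymphocyte markers. Adjusted over the list alone, 1 lymphocyte marker was lower, 1 glucocorticoid-responsive gene was higher, and 3 immediate early genes were lower and 1 higher.

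No single probe passed the test between the overloads. With limma, 0 of 10234 probes passed (smallest adjusted p = 0.50), 647 had an unadjusted p under 0.05, and 0 passed under each alternative setting run. Ms4a4c and Rad17 had the smallest p, but both were above background in only 1 of 4 systolic hearts, so that their log2 differences (−0.62 and −0.57) are imprecise in size. Fkbp10, a collagen chaperone of the endoplasmic reticulum, and Pgrmc1 had lower means under systolic overload (−0.45 and −0.47). Amd1, an enzyme of polyamine synthesis, stood at 10.29 ± 0.20 against 9.65 ± 0.26 (1.55-fold, adjusted p = 0.51), and Fbxo32, the muscle ubiquitin ligase atrogin-1, at 6.48 ± 0.13 against 5.89 ± 0.18 (1.5-fold, adjusted p = 0.54), each higher in 4 of 4 systolic hearts. Higher means were also found for Traf4 (0.56, above background in 1 of 4 diastolic hearts), Rapgef2 (0.46) and Zfp638 (0.47).

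**Figure D2:**
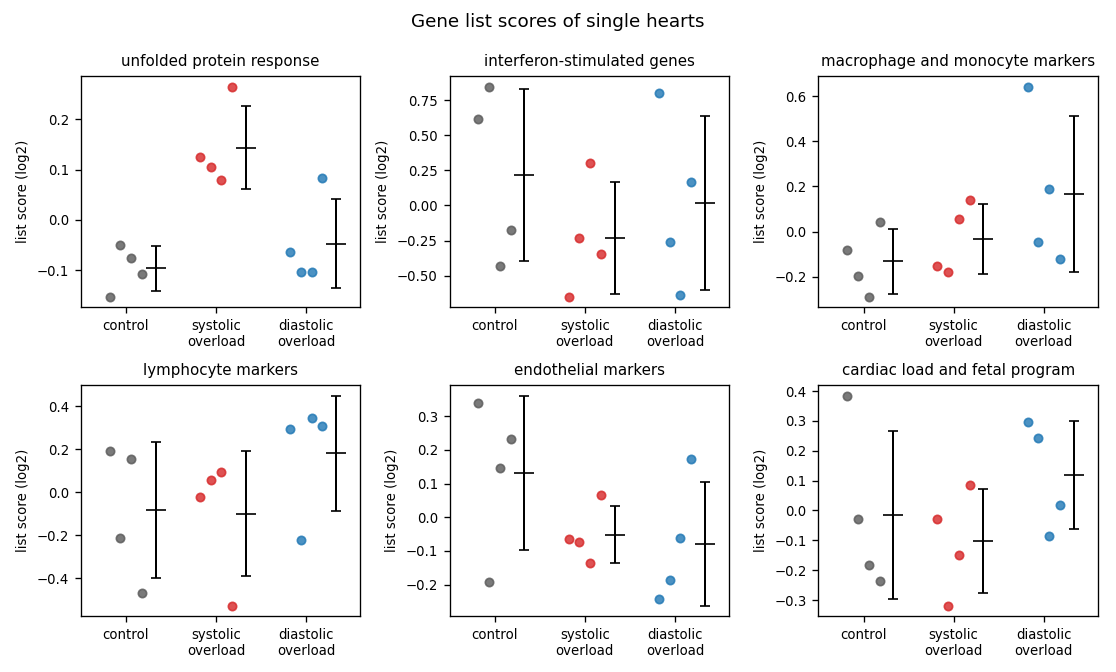
Scores of 6 gene lists for each of the 12 hearts by group, in log2 relative to the mean of all hearts, with group means and bars of 1 SD. Unfolded protein response scores of the systolic overload hearts, 0.08 to 0.27, lay above all control scores, while interferon scores spread over 1.5 in log2 with overlapping groups.

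The 2 overload effects, each against the same controls, correlated across the 10234 tested probes at r = 0.49, and unchanged groups simulated against shared controls gave 0.50 on average (0.47 to 0.55). Genes are not independent replicates here. The covariance was 0.015 against a simulated 0.013. With the controls split 2 and 2, so that each overload had its own controls, r was −0.0019 on average over 6 splits (−0.16 to 0.15). Smoc2 was the 1 gene among the 10 with the smallest p in both contrasts against control, and its 8 overloaded hearts shared the same 4 controls.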

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

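All tests against other splits of the hearts, both tests on interferon-stimulated genes and the test on probes with separate levels were set down only after their results were seen, whereas the tests of brightness and cell mix for the unfolded protein response were set down before theirs.

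By camera at its preset correlation, 9 gene lists differed directly between the overloads, of which 0 were called with an estimated correlation (smallest adjusted p = 0.55). Fry, whose null is no change and not likeness to other genes, called 0 of them in its directional test, and simulated unshifted lists with correlated members gave 3.60 calls per contrast. The 9 lists had a median log2 difference, systolic minus diastolic, of 0.21 for the unfolded protein response, 0.095 for fatty acid oxidation, 0.13 for glucocorticoid-responsive genes, −0.17 for cardiac load genes, −0.14 for extracellular matrix, −0.24 for interferon-stimulated genes, −0.14 for macrophage markers, −0.21 for lymphocyte markers and −0.089 for immediate early genes.

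Higher unfolded protein response genes under systolic overload were the pattern with the smallest list p by camera, though not by fry. Of the 35 splits of the 8 systolic and control hearts, 1, the real one and the fewest possible, gave this list so small a p (−log10 p of 9.65, highest other 5.92), and likewise 1 of 35 for systolic against diastolic hearts (7.96, highest other 7.82), yet some list reached a p as small as the smallest real one in 6 and 8 of the 35 splits (highest others 16.2 and 16.1), so chance is not excluded once the choice among lists is counted. A shift shared by equally bright genes was argued against. Of 10000 random lists matched on mean level, 0% reached the median of 0.23 (highest 0.12). The random genes lack the correlation of the list's members (estimated at 0.15), so the 0% is no test against chance. Another mix of cardiomyocytes and endothelium was argued against only as far as their marker scores measure it. The difference in list score was 0.27 with both marker scores as covariates (95% interval 0.07 to 0.47) and 0.24 without. The cardiomyocyte score itself separated the groups, at 0.02 to 0.03 in systolic hearts and −0.13 to 0.01 in controls. Its markers include Myh6, near the top of the array's range, so the adjustment may be incomplete. Other cell types were not tried as covariates. The load in systole, which the design names, remains an open and untested cause, and these data are consistent with it as a hypothesis.

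Interferon-stimulated genes differed between hearts of one group, with scores from −0.43 to 0.85 in control, −0.65 to 0.30 under systolic and −0.64 to 0.80 under diastolic overload. Mx1 ran from 8.59 to 11.03 in control and from 7.91 to 10.81 under diastolic overload. Macrophage and lymphocyte content, with both cell types moving together, was argued against as the sole source. Their marker score moved by 0.13 log2 per log2 of interferon score within groups (95% interval −0.11 to 0.37). Cells carrying the signal would need about 1, if both cell types moved together and both scores followed cell number alike. A smaller slope would do if only 1 of the cell types carried the signal, since the score averages both marker lists. That case was not tested. Changes of dim markers such as Cd3d (5.06 to 6.55) are understated, which lowers the slope to be expected. A shift shared by equally bright genes was argued against. Of 10000 matched random lists, 0% varied as much within groups (SD 0.55, highest random 0.17). Interferon-stimulated genes vary together (estimated correlation 0.70) and random genes need not, so the 0% is no test against chance. No other biological explanation was tested, since the labels name nothing that divides the hearts of a group.

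At 10 probes the hearts fell on 2 separate levels at least 1 log2 apart, against 2 such probes in simulated normal values. They included RT1-A2 and RT1-A1, class I genes of the major histocompatibility complex (gaps of 2.15 and 1.36), Pxmp4 (2.07), Mrpl17 (1.79), Hmgn1 (1.72) and Vegfb (1.55). RT1 genes were 2 of the 6 named ones and 21 of 7473 named probes tested (Fisher's exact p = 0.00011, on a pattern seen first). A candidate explanation is sequence variants under the probes in outbred animals, which cannot be told apart from real differences in expression, because 0 other probes of these genes were tested.

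The numbers of called lists were reached by other splits too. As many lists as the real 5, 7 and 9 were called in 14, 14 and 4 of the 35 splits for systolic against control, diastolic against control and systolic against diastolic (highest others 7, 11 and 11). In diastolic overload against control, some list reached a p as small as the real one in 27 of 35 splits (−log10 p of 4.84, highest other 30.1, for interferon-stimulated genes). Chance can therefore not be excluded for these list counts. For probes the splits test nothing, since each of the 35 necessarily gave at least the real count of 0 in each contrast (highest others 0, 1 and 3).

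One heart lay far from the others of its group in 18 of 264 groups of values checked, where chance alone gives about 1 in 20, or 13.2. In control these were Myh6 in replicate 2 (14.44, others 14.64 to 14.65), Nccrp1 in replicate 2 (5.74), Or10ag54b in replicate 3 (5.96), Acot1 in replicate 3 (7.64, others 6.54 to 6.72) and the NRF2 score in replicate 3 (−0.17). Under systolic overload they were Ankrd1 in replicate 2 (14.74), Nccrp1 in replicate 3 (5.24), Cldn5 in replicate 3 (9.39, others 10.32 to 10.45), Traf4 in replicate 3 (5.47) and Cdkn1a in replicate 1 (8.68, others 8.13 to 8.17). Under diastolic overload they were Emcn in replicate 1 (10.42), Ier3 in replicate 1 (11.49), Traf4 in replicate 2 (5.45), Mpzl1 in replicate 4 (6.93), Rad17 in replicate 4 (5.71), and the scores of heat shock proteins in replicate 2 (−0.014), lymphocyte markers in replicate 2 (−0.22, others 0.29 to 0.35) and glucocorticoid-responsive genes in replicate 4 (0.13, others −0.25 to −0.21).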

How the results depend on the processing

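The residual component covariate, the 3 arrays left out together (control 1, control 4 and diastolic overload 1) and the list scores were chosen after seeing the data. The 3 probe counts were 0 under all 25 alternatives each. Among these, the stricter thresholds on the main fit could give nothing but 0. The unfolded protein response list kept its direction and its call in both contrasts under every other normalization, filter, weight and left-out array, with medians of 0.16 to 0.27 and 0.13 to 0.25 with 1 array left out; with an estimated correlation its medians of 0.23 and 0.21 no longer passed, nor did they with fry and list scores, which test against no change. The 21 list calls over 3 contrasts (5, 7 and 9) became 0 with an estimated correlation, with fry and with list scores, and 4 (2, 0 and 2) with fry in either direction, 2 of them the unfolded protein response. They were 13 (3 and 4 in the contrasts against control) with detection p under 0.01 on all arrays, 12 (diastolic against control 4, systolic against diastolic 3) without the 3 arrays, and 12 to 22 with 1 array left out (2 to 6, 3 to 8 and 3 to 9), with totals of 12 without systolic overload 1, systolic overload 3 or diastolic overload 1 and 13 without diastolic overload 3. The count fell to 2 or 3 in systolic against control without control 2, control 4, systolic overload 1, 2 or 3, or diastolic overload 1 or 3, to 3 or 4 in diastolic against control without control 4 or diastolic overload 2 or 3, and to 3 to 5 in systolic against diastolic without systolic overload 1, 3 or 4 or diastolic overload 1. Median scaling gave 8 lists for systolic against control and array weights 3, and array weights gave 5 for systolic against diastolic. Median scaling also moved the median of all tested probes to −0.17 and −0.18 against control, so that its list medians are relative to these, and gave 1198, 1369 and 333 probes at an unadjusted p under 0.05, of which 1150 and 1314 were lower in the contrasts against control. Without the detection filter these were 1254, 1261 and 1328. Without the 3 arrays, camera's direction turned for endothelial markers under systolic and diastolic overload (medians 0.00843 and −0.0383, adjusted p = 0.97 and 0.93), and for extracellular matrix in systolic against diastolic (−0.0207). The latter also turned without diastolic overload 1, with medians of −0.286 to −0.0210 over the 12 arrays left out. The correlation of the overload effects was 0.61 without the 3 arrays and 0.40 to 0.62 with 1 left out, the highest without control 3. Shared controls alone gave a mean r of 0.50 in simulated unchanged groups of the full size. That value depends on the number of hearts per group and was not simulated with arrays left out. The changes in r therefore do not show that the overload effects became more or less alike, and their cause was not tested. Of 103 values of named genes, 26 changed sign under at least 1 alternative, all of them among the genes fixed in advance. With the replicate number as a block, 0 probes passed and 17 lists were called (4, 6 and 7), and the unfolded protein response calls held. The numbers were not shown to pair the hearts, as same-numbered hearts correlated in their deviations at −0.27 to 0.33, with 2 of 12 pairs over 0.1, and 4 of 12 hearts matched best to their own number. The slide block was not run because the file gives no slide. Signal over background limits dim genes such as Fyttd1, Frs2, Nccrp1 and Slc43a2, which were near the detection limit.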

Other observations

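Values of 2 genes, neither of which passed the test, are given here after they were seen. Trim63, the muscle ubiquitin ligase MuRF1, stood at 11.04 ± 0.24 under systolic overload, 10.48 ± 0.21 in control and 10.59 ± 0.23 under diastolic overload (SD, n = 4 each; adjusted p = 0.66 against control), and its groups did not overlap against control. Its list, the ubiquitin-proteasome and autophagy genes, was not called by camera in either comparison of systolic overload (20 of 32 members higher against control, adjusted p = 0.087; 23 of 32 against diastolic overload, adjusted p = 0.32), but fry's test in either direction gave adjusted p = 0.0087 against control and 0.0042 against diastolic overload. Fkbp5, a co-chaperone induced by glucocorticoids, stood at 11.25 ± 0.19 under systolic overload, 10.46 ± 0.33 in control and 10.77 ± 0.36 under diastolic overload (adjusted p = 0.52 against control).

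Camera did not call the lists of oxidative phosphorylation, cytosolic ribosomal proteins or sarcomere genes. Oxidative phosphorylation genes had a median log2 difference of 0.0024 and −0.0048 under systolic and diastolic overload against control over 40 genes, and cytosolic ribosomal proteins 0.012 and 0.011 over 38. Sarcomere genes stood at 0.06 and 0.07 over 25 genes (adjusted p = 0.11 and 0.093), as far from 0 as some lists that were called. The adjusted p of the other 4 tests was 0.45 to 0.95. Single hearts stood apart in other ways. Control 1 had the highest score of atrial markers (0.53), and diastolic overload 1 that of extracellular matrix genes (0.78) and macrophage markers (0.64). Erythroid markers did not single out 1 heart, as control 1 (0.65) was close to control 4 (0.62).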
